A study of Homo sapiens with 4 samples.

How the data were processed

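The series holds 4 microarrays of human primary erythroid cells grown in culture from CD34+ blood stem and progenitor cells. Per the labels, all cells were collected on day 8 of culture. Per the labels' protocols, the medium contained erythropoietin, stem cell factor and other growth factors, and tranylcypromine (TC) in water was present from day 4 at 0.5, 1.5 or 5 µM. An array of cells with no drug served as the untreated sample. Its label gives day 8, while the series' design text speaks of cells taken before or after treatment, so it is not settled whether this was a parallel culture of the same donor. Each dose, the untreated sample included, is represented by 1 array, so there were no replicates, and the labels do not say whether the cultures came from 1 or several donors. Groups were taken from the drug treatment given in the labels for each sample.

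Per the labels' protocols, total RNA was extracted with Trizol, and biotin-labelled RNA was made from 250 ng of it with the Affymetrix 3' IVT Express kit, which copies messages from their poly(A) tails and therefore favours their 3' ends. Per the submitters' processing notes, RMA, affy and limma were used. Their versions, their order and the background correction were not given in the sources used here. The deposited values are log2 expression values, 1 per probe set and array, for 49386 probe sets. On the untreated array they ran from 2.72 to 13.61, and the array medians lay between 5.08 and 5.10. After sorting, the values of the 4 arrays differed by 0.0275 on average, as values do after normalization between arrays. Such scaling hides any change in the total amount of message per cell, so every difference given here is relative to the other genes on the array. RMA can also compress differences of very dim and very bright probe sets. The values carry no read counts or depth, and the number of arrays limits their precision.

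Probe sets were named through the platform annotation table supplied with the values. Of the 49386 probe sets, 45259 had 1 gene symbol, 1327 had several, 2800 had none in that table and 93 of all probe sets were controls. Gene numbers of 45178 of the 45259 probe sets with 1 symbol were found in the RefSeq gene table of assembly GRCh38.p14, which was used only for names. No coordinates are given, because the values name no genome build. A gene was represented by its probe set with the highest mean over the 4 arrays among probe sets with 1 symbol. This gave 18239 genes. Those with a mean above the 40th percentile of all probe sets (4.53 on the log2 scale) were kept, which left 12713 genes. Probe sets with no symbol or several were used in no comparison of genes, so the alpha-globin genes HBA1 and HBA2 and the fetal globin gene HBG2 were not analysed here. Genes whose level could describe a donor were not named.

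The choices described in this paragraph and the next were made before the data were examined. For each dose, the log2 difference from the untreated array was computed, and genes with a difference of 2-fold or more (an absolute log2 difference of at least 1) were counted. A difference between 2 single arrays has no replicate error, so no p-value is given for it. The only test was a trend over the 4 arrays, with the dose step (0, 1, 2 and 3 for 0, 0.5, 1.5 and 5 µM) as a numeric covariate, fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3. It has 2 residual degrees of freedom, to which the fit across genes added 3.28 prior degrees of freedom. Benjamini-Hochberg adjustment ran over the 12713 genes, and a gene is said to have risen or fallen where the adjusted p was under 0.05. The error in this test is the scatter about a straight line over 4 arrays. The labels name no separate cultures of 1 dose, so it does not measure the spread between repeated cultures.

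A set of 39 gene lists (cell type markers, pathways and complexes) was fixed, and 36 of them had at least 5 measured genes. The lists hold 653 different genes, of which 538 were measured, 66 lay below the expression filter and 49 had no probe set with 1 symbol. Each list's median difference was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list is said to stand apart below the 2.5th or above the 97.5th percentile. Genes are not replicates, so this percentile describes these arrays and is no test. Within each list, the trend test was also adjusted over the list alone. Genes named in the text are the 12 with the largest difference in each direction at 5 µM among those at 2-fold or more with the same sign at each dose, the 5 largest in each direction at 1.5 and 0.5 µM, and the 5 with the smallest trend p in each direction. To these were added all measured members of the lists of globins, fetal globin repressors, the LSD1-CoREST complex and monoamine oxidases, and up to 4 members of each other list with the largest difference at 5 µM. The rule gave 193 genes.

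Differences against the untreated array share that array and so correlate by chance. They were therefore also correlated between pairs of arrays with none in common, and the shared-array values were set beside a simulation with no effect. The trend script was tested on simulated data for 12713 genes. At a slope of 0.5 per step, 66 of 66 changed genes were recovered, and likewise 66 of 66 at a slope of 1. At a slope of 0.2, 30 of 68 were recovered, and 10 genes with no change were called. In a simulation of gene lists, 20 of 20 lists shifted by 0.3 were found and 3 of 40 lists with no shift were called. Its genes varied independently with an SD of 0.2, where the SD of the real 5 µM differences across genes was 0.52. These rates therefore need not hold for the real lists. Lists and figures were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

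Alternatives tried were 3 further normalizations of the deposited values (centring each array on its median, cyclic loess and quantile), the mean of all probe sets of a gene, leaving out probe sets whose names end in _x_at (these share probes between transcripts), no expression filter or the 60th percentile, a 1.5-fold threshold, other codings of dose, a variance prior with trend and robust settings, and leaving out each array in turn. After the control probe sets had been seen to differ on the untreated array, TC 0.5 µM was added as another baseline. Cyclic loess was added for the correlations at the same point. Scan dates and array batches were not used here.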

Results

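Gene expression was measured in human primary erythroid cells on day 8 of culture, with tranylcypromine (TC) present from day 4 or with no drug. TC is an irreversible inhibitor of the monoamine oxidases and also inhibits LSD1 (KDM1A), a histone demethylase that works with the CoREST proteins and takes part in silencing the fetal globin genes. The samples were untreated cells and cultures with 0.5, 1.5 or 5 µM TC, each hybridised to 1 array. The values are the deposited log2 expression values of 12713 genes above the expression filter. There were no replicates at any dose, and the number of arrays limits the precision of every value. Across all probe sets, the untreated array correlated with the TC arrays at r = 0.996 (0.5 µM), 0.991 (1.5 µM) and 0.983 (5 µM), correlations across probe sets, which are not independent replicates.

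The comparison of 5 µM TC with no drug asks what the highest dose did to the cells' expression program. The largest increases were in RUNX2, a transcription factor best known from bone formation, at 4.61 on the log2 scale, in ITGAM, an integrin of myeloid cells, at 4.52, in LY96, a partner of the endotoxin receptor, at 4.46, and in IKZF2, an Ikaros-family transcription factor, at 4.43. SIGLEC6, VIM (vimentin, an intermediate filament protein), CTSS (cathepsin S) and SOX4 followed at 4.26, 4.21, 3.88 and 3.87. On the untreated array RUNX2, ITGAM, LY96, IKZF2, SIGLEC6 and CTSS lay between 3.36 and 4.42, below the filter value of 4.53. They passed the filter through their mean over the 4 arrays. The sizes of their increases thus start from untreated values close to background. Among the largest decreases, HBM, an alpha-like globin gene, differed by −4.55, THBS1 (thrombospondin) by −4.44, TRIM10 by −4.37 and FHDC1 by −4.18. HEMGN (hemogen, a nuclear protein of red cell precursors) differed by −4.10 and SLC4A1, the anion exchanger of the red cell membrane, by −4.01. In all, 514 genes were higher by 2-fold or more and 207 were lower, together 5.67% of the 12713 genes. Of the counts at this dose, that of higher genes was 313 with the mean of all probe sets of a gene and 327 with the 0.5 µM array as the baseline.

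Each of these genes passed the trend test over the 4 arrays. RUNX2 rose by 1.58 ± 0.0805 (SE) per dose step (limma adjusted p = 0.0039), and HBM fell by 1.59 ± 0.105 (limma adjusted p = 0.0040). With the 5 µM array left out, ITGAM, LY96 and IKZF2 no longer passed (limma adjusted p = 0.098, 0.113 and 0.0881), whereas the other genes named above passed without any single array. GPR183, SLC25A24 and PLPP1, at 3.68, 3.55 and 3.51, completed the largest increases among genes with the same sign at each dose. With them was GPAT3, which was higher by 3.40 but did not pass (limma adjusted p = 0.0515). On the untreated array GPR183, SLC25A24 and GPAT3 also lay below the filter value of 4.53, at 3.91, 3.86 and 3.85. By the same rule PAQR9, MGST3, PPBP, SOX6, ADM and ZDHHC14 completed the largest decreases, at −4.09, −3.88, −3.74, −3.32, −3.17 and −3.11. Without the 5 µM array GPR183, PLPP1 and ZDHHC14 did not pass (limma adjusted p = 0.13, 0.103 and 0.0831). The size of a difference depended on the probe set in several of these genes. With the mean of all probe sets of a gene, RUNX2 was higher by 2.32, ITGAM by 2.58 and SLC25A24 by 1.78. By that measure THBS1 was at −1.58, TRIM10 at −2.46, PAQR9 at −2.52, SOX6 at −1.72 and ADM at −1.96. The other RUNX2 probe set above the expression filter differed by only 0.04 at 5 µM, so the increase of RUNX2 rests on a single probe set.

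Lists of erythroid genes were lower at 5 µM. The median of the 14 measured genes of heme synthesis and mitochondrial iron handling was −1.04, where 95% of matched random lists lay between −0.15 and 0.10. In this list 10 genes fell and 0 rose (12 fell when adjusted over the list alone). ALAS2, the erythroid enzyme that starts heme synthesis, fell by 0.75 ± 0.0425 per step and differed by −2.20 at 5 µM (limma adjusted p = 0.0039). SLC25A37 (mitoferrin, the mitochondrial iron importer) was at −1.59, UROS at −1.51 and SLC25A39 at −1.41. Among 20 red cell enzymes and late erythroid genes 13 fell and 0 rose (15 and 0 adjusted over the list alone), with a median of −0.68. They include SLC2A1, the glucose transporter, at −1.77, TSPO2 at −1.82 and BPGM, which makes the regulator of oxygen release, at −2.11. Among 15 genes of the red cell membrane and surface 8 fell and 0 rose (11 and 0 adjusted over the list alone), with a median of −0.63. Their largest decreases after SLC4A1 were in ADD2 at −1.64, SPTB (beta spectrin) at −1.43 and DMTN (dematin) at −1.38. With the mean of all probe sets these 3 genes were at −0.88, −0.57 and −0.87, and without probe sets that share probes between transcripts DMTN was at −0.29.

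Transcription factors of the erythroid lineage were lower as a list, with a median of −0.43 over 14 genes. Of these 5 fell and 2 rose (8 and 2 adjusted over the list alone). E2F2 was at −1.35, KLF3 at −1.05 and MXI1 at −0.91, and ZFPM1 (FOG1, the GATA1 partner) fell by 0.34 per step. KLF1, which switches on adult beta-globin and many red cell genes, was lower, at −0.45, and did not pass (limma adjusted p = 0.0862). Of the erythroid genes named so far, UROS, SPTB, KLF3, ZFPM1 and MXI1 did not pass the trend test without the 5 µM array (limma adjusted p = 0.0933, 0.0675, 0.0528, 0.0818 and 0.0772), nor E2F2 and BPGM without the untreated array (0.0506 and 0.0529). GATA1, TAL1, LMO2 and LDB1, named after their values were seen, were at −0.24, −0.40, −0.21 and −0.17. None of them passed (limma adjusted p between 0.0975 and 0.68). In this list the 2 that rose were GFI1B, at 0.71, and LYL1, named likewise, at 0.65 (limma adjusted p = 0.0383 and 0.0245).

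Control probe sets moved over the same arrays as the erythroid lists. Those for 18S ribosomal RNA were higher than on the untreated array by 0.72, 0.46 and 0.81 in order of dose, and the probe set for the 5' end of ACTB by 0.26, 0.58 and 0.64, against −0.02, 0.14 and 0.18 for its 3' end. The 5' end of GAPDH differed by 0.25, 0.27 and 0.19. Set against the 0.5 µM array in place of the untreated array, the heme list at 5 µM had a median of −0.71, the red cell enzyme list −0.44, the membrane list −0.51 and the erythroid transcription factor list −0.42.

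**Figure D1:**
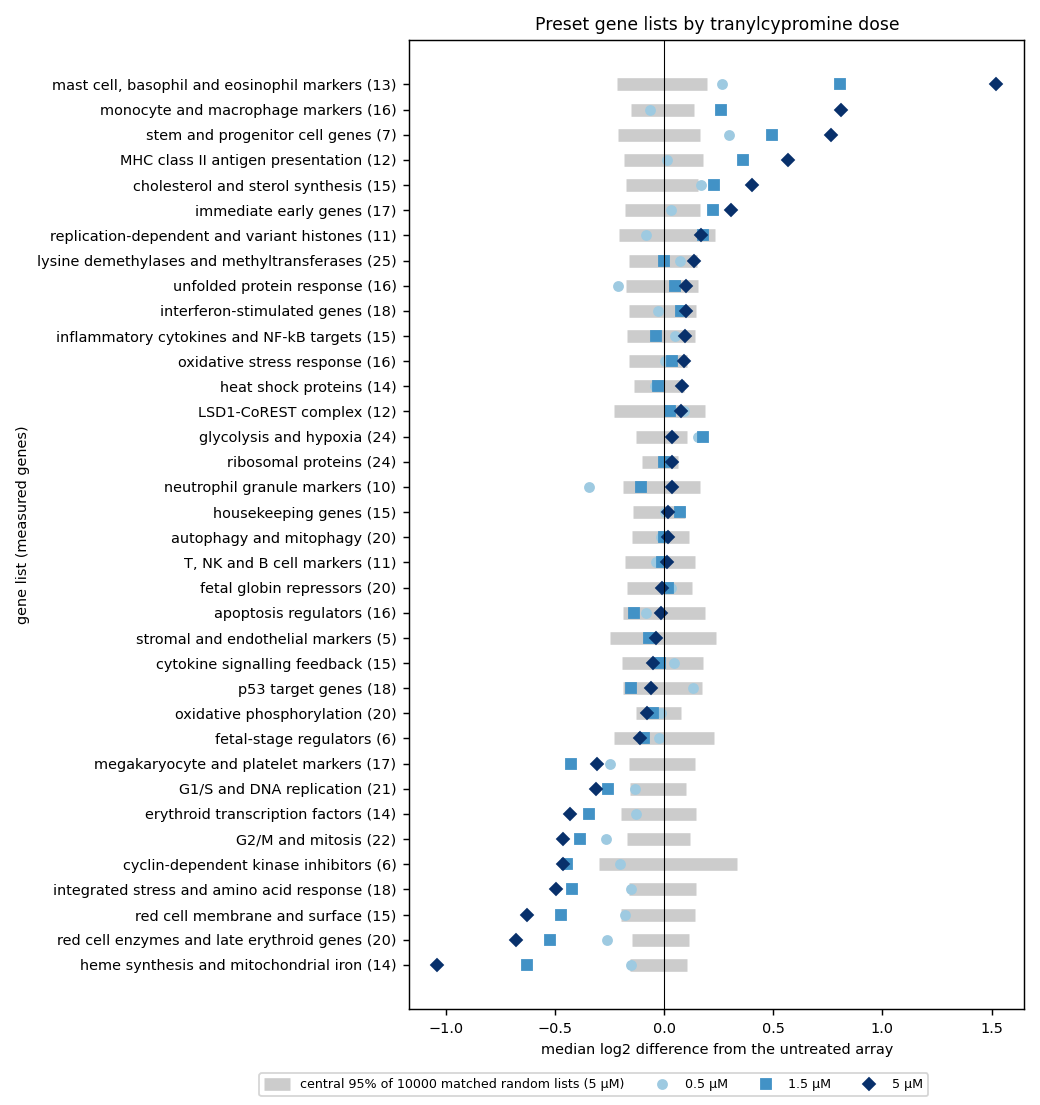
Median log2 difference from the untreated array (horizontal axis) of each preset gene list (vertical axis, with its number of measured genes) at each TC dose (0.5, 1.5, then 5 µM), 1 array per dose. Grey bars hold the central 95% of 10000 random lists matched on expression at 5 µM. The list of mast cell, basophil and eosinophil markers lies at 1.52 and that of heme synthesis at −1.04 at the highest dose.

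The globin genes, whose switch from the fetal to the adult form LSD1 is known to influence, did not move together. HBB, the adult beta-globin gene, was at 13.43 on the untreated array and 13.28 at 5 µM, a difference of −0.15 (limma adjusted p = 0.381), or −0.07 after quantile normalization. HBG1, a fetal gamma-globin gene, differed by −0.16 (limma adjusted p = 0.36) and the embryonic HBE1 by −0.08 (limma adjusted p = 0.821). HBD, the minor adult delta-globin gene, fell by 0.32 ± 0.0381 per step to −0.95 at 5 µM (limma adjusted p = 0.0106). Among the alpha-like genes, HBM was lower, at −4.55, as was HBQ1, at −1.18 (limma adjusted p = 0.0069). HBZ, an embryonic gene, was lower, at −0.93, without passing (limma adjusted p = 0.104). Against the 0.5 µM array HBM, HBQ1 and HBZ were at −3.36, −0.90 and −0.12. HBD and HBQ1 did not pass without the 5 µM array (limma adjusted p = 0.101 and 0.054). The probe sets of HBB and HBG1 are of a kind that shares probes between transcripts, so the value of HBG1 cannot be separated from that of its near-identical copy. Both lay close to the highest value of the untreated array, 13.61, where array signals can compress differences.

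**Figure D2:**
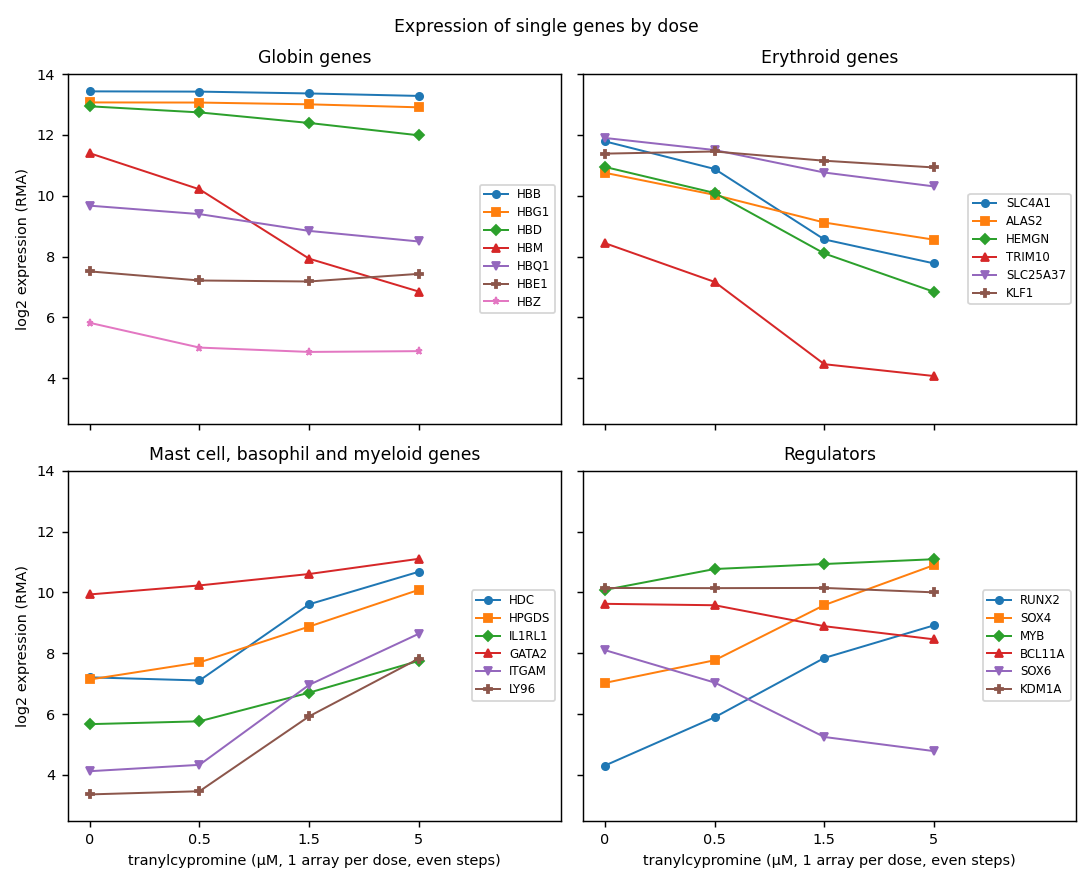
Log2 expression (vertical axis) of single genes on the untreated array and at rising TC doses in µM (horizontal axis, even steps), 1 array per point, so no error bars are drawn. HBB went from 13.43 to 13.28, SLC4A1 from 11.79 to 7.78, HDC from 7.21 to 10.68 and RUNX2 from 4.31 to 8.91 between no drug and 5 µM.

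Known repressors of the fetal globin genes went in different directions, and their list did not stand apart (median −0.01 over 20 genes, 1 rose and 2 fell; 2 and 2 adjusted over the list alone). SOX6 fell by 1.17 ± 0.111 per step (limma adjusted p = 0.0067). BCL11A, the main silencer of gamma-globin in adult cells, fell by 0.42 ± 0.0631 per step and differed by −1.17 at 5 µM (limma adjusted p = 0.0187), or by −0.68 with the mean of its probe sets. MYB, a progenitor transcription factor, rose by 0.32 ± 0.0647 per step and was higher by 1.01 (limma adjusted p = 0.0382). Neither BCL11A nor MYB passed without the 5 µM array (limma adjusted p = 0.146 and 0.0871) or the 1.5 µM array (0.0526 and 0.0907), and MYB did not without the untreated array either (0.16). CHD4 was higher by 0.85, or 0.45 with the mean of its probe sets (limma adjusted p = 0.0614). Against the 0.5 µM array MYB was higher by 0.32 and CHD4 by 0.23, while SOX6 and BCL11A were at −2.25 and −1.12. IKZF1, EHMT1, EHMT2, MBD2, MBD3, GATAD2A, MTA2, NR2C1 and NFIX were between −0.02 and 0.33, and NFIA, DNMT1, ZBTB7A and NR2C2 between −0.35 and −0.07, without passing. Another probe set was at −0.86 for NFIX, −1.10 for NFIA, −0.51 for NR2C2 and 0.50 for GATAD2A.

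Messages of the drug's known targets were looked at next. KDM1A itself was lower, at −0.14 (limma adjusted p = 0.501), and the LSD1-CoREST list did not stand apart (median 0.08 over 12 genes, 2 rose and 0 fell; 2 and 0 adjusted over the list alone). The 2 that rose were GFI1, at 0.91 (limma adjusted p = 0.0406), and GFI1B, at 0.71 (limma adjusted p = 0.0383), repressors that recruit LSD1 to DNA. GFI1B lost the call without any of the 4 arrays (limma adjusted p between 0.0513 and 0.224), and GFI1 without the untreated, 0.5 µM or 5 µM array (0.0522, 0.0813 and 0.284), and GFI1 was at 0.57 with the mean of its probe sets. RCOR1, RCOR3, HDAC1, HDAC2, HMG20B, PHF21A, ZMYM2, ZMYM3 and GSE1 differed by −0.16 to 0.37 and did not pass. Both monoamine oxidase genes rose. MAOA was higher by 1.56 (limma adjusted p = 0.0103) and MAOB by 1.68 (limma adjusted p = 0.0332). MAOB did not pass without the 5 µM or the 1.5 µM array (limma adjusted p = 0.225 and 0.0627), and with the mean of all probe sets the increases were 0.93 and 0.85.

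Genes of mast cells, basophils and eosinophils were the list that stood furthest above the random lists at 5 µM, with a median of 1.52 over 13 genes against a random range of −0.22 to 0.20. Of them 9 rose and 0 fell (10 and 1 adjusted over the list alone), and 2 of the 13 are also in the progenitor list. HDC, which makes histamine, was higher by 3.47 (limma adjusted p = 0.0229), HPGDS, a prostaglandin D synthase, by 2.94 (limma adjusted p = 0.0045), IL1RL1, the receptor of interleukin 33, by 2.08 (limma adjusted p = 0.0169), and FCER1A, a chain of the IgE receptor, by 1.75 without passing (limma adjusted p = 0.11). Monocyte and macrophage markers had a median of 0.81 over 16 genes, of which 5 rose and 1 fell (9 and 2 adjusted over the list alone). LYZ, the lysozyme gene, was higher by 2.71 (limma adjusted p = 0.0362), beside ITGAM, LY96 and CTSS. Another 10 monocyte genes, CD14 and S100A8 among them, lay below the expression filter. HDC and LYZ did not pass without the 1.5 µM or the 5 µM array (limma adjusted p up to 0.153 and 0.251), nor did IL1RL1 without the 5 µM array (0.112), and IL1RL1 was at 0.88 with the mean of its probe sets.

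Further lists above the random range were progenitor genes, antigen presentation genes, sterol synthesis and immediate early genes. Stem and progenitor cell genes had a median of 0.77 over 7 genes, with 5 that rose and 0 that fell (5 and 0 adjusted over the list alone), among them GATA2, a progenitor and mast cell transcription factor, at 1.17, CD109 at 1.16 (0.45 with the mean of its probe sets) and MECOM at 0.77. Without the expression filter, which brings in the genes below it, the median of that list was −0.03. Of 12 genes of MHC class II antigen presentation 6 rose and 0 fell (6 and 1 adjusted over the list alone), with a median of 0.57, HLA-DRA at 2.39 and HLA-DPA1 at 1.63. Cholesterol and sterol synthesis had a median of 0.40 over 15 genes, with 4 that rose and 0 that fell (8 and 0 adjusted over the list alone), HSD17B7 at 1.01, HMGCS1 at 0.80, MSMO1 at 0.80 and IDI1 at 0.71. Immediate early genes had a median of 0.31 over 17 genes, with 4 that rose and 2 that fell (6 and 3 adjusted over the list alone). EGR3 and EGR1, growth factor response genes, were higher by 2.75 and 1.68, while ATF3 was lower, at −1.70. Of the genes in this paragraph, HLA-DPA1 and EGR1 passed without any single array. ATF3 lost the call without the untreated array (limma adjusted p = 0.0552), and the others lost it without the 5 µM array (between 0.0506 and 0.316). Among those, CD109, MECOM, HLA-DRA, HMGCS1, MSMO1 and IDI1 also lost it without the 1.5 µM array (limma adjusted p between 0.054 and 0.095), EGR3, MSMO1 and IDI1 without the 0.5 µM array (0.0604, 0.056 and 0.07), and MECOM, HMGCS1 and IDI1 without the untreated array (0.123, 0.127 and 0.0654). The control probe sets for 18S RNA and the 5' end of ACTB were higher on the same arrays, and against the 0.5 µM array the mast cell list had a median of 0.96, the monocyte list 0.93, the progenitor list 0.33, the MHC class II list 0.42, the sterol list 0.19 and the immediate early list 0.31.

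Markers of megakaryocytes and platelets were lower as a list, with members that moved both ways. Their median was −0.31 over 17 genes, with 8 that fell and 2 that rose (9 and 3 adjusted over the list alone). Besides THBS1 and PPBP, the platelet chemokine gene PF4 was lower, at −2.73 (limma adjusted p = 0.0067) and LTBP1 at −2.57 (limma adjusted p = 0.0071), PF4 losing the call without the 5 µM array (limma adjusted p = 0.0506). The 2 that rose, named after their values were seen, were ITGA2B, a platelet integrin gene, higher by 1.40 at 5 µM (limma adjusted p = 0.0288), and RUNX1, a blood cell transcription factor, which went from 8.17 with no drug to 9.27 (limma adjusted p = 0.0233). With the mean of their probe sets these 2 genes were higher by 0.64 and 0.45. FLI1, also a transcription factor and named likewise, was higher by 2.55 without passing (limma adjusted p = 0.0602). ITGA2B did not pass without the 5 µM or the 1.5 µM array (limma adjusted p = 0.212 and 0.0624), nor RUNX1 without the 5 µM or the untreated array (0.184 and 0.0848). Against the 0.5 µM array the list's median was −0.36. Neutrophil granule markers did not stand apart at 5 µM (median 0.04 over 10 genes, 1 rose and 2 fell; 1 and 3 adjusted over the list alone), but lay below the random range at 0.5 µM (−0.34). MPO and ELANE, enzymes of neutrophil granules, were lower, at −1.63 and −1.60, and CST7 was higher by 0.72. Each of these lost the call without 2 of the arrays, MPO and ELANE with the highest p without the untreated array (limma adjusted p = 0.17 and 0.0977) and CST7 without the 5 µM array (0.131). Markers of T, NK and B cells (median 0.01 over 11 genes) and of stromal and endothelial cells (−0.04 over 5 genes) did not stand apart, and in both lists 0 genes rose or fell by limma, also when adjusted over the list alone.

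Cell cycle lists were lower as well. The G1/S and DNA replication list had a median of −0.31 over 21 genes, with 6 that fell and 0 that rose (13 and 0 adjusted over the list alone), CCNE1 (cyclin E1) at −1.38 among them. The G2/M and mitosis list had a median of −0.46 over 22 genes, with 6 that fell and 0 that rose (12 and 0 adjusted over the list alone), MKI67, CENPE, CDC20 and AURKA lying between −0.72 and −0.58. With the mean of their probe sets MKI67 was at −0.29 and CDC20 at −0.41. CCNE1 passed without any single array, while the 4 mitosis genes did not pass without the untreated array (limma adjusted p between 0.112 and 0.276) or the 5 µM array (between 0.054 and 0.261). CENPE, CDC20 and AURKA did not pass without the 1.5 µM array either (limma adjusted p = 0.083, 0.091 and 0.0841), nor CENPE and AURKA without the 0.5 µM array (0.0731 and 0.0604). Inhibitors of the cyclin-dependent kinases had a median of −0.46 over 6 genes, of which 1 fell, CDKN1C at −1.37 (1 adjusted over the list alone), which did not pass without the 5 µM or the 0.5 µM array (limma adjusted p = 0.165 and 0.0757). CDKN1C was at −0.76 with the mean of its probe sets and at −0.17 without those that share probes between transcripts. Against the 0.5 µM array, on which it was already at −0.20 and below the random range, this list did not stand apart (median −0.01), nor without probe sets that share probes between transcripts (−0.17). The same baseline gave −0.21 for G1/S and −0.16 for G2/M.

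Stress lists differed from each other. The integrated stress and amino acid response had a median of −0.50 over 18 genes, with 6 that fell and 0 that rose (11 and 0 adjusted over the list alone). ASNS, the asparagine synthetase gene, fell by 0.60 ± 0.0561 per step to −1.70 at 5 µM (limma adjusted p = 0.0066), TRIB3 was at −1.42 and SLC7A11, the cystine transporter, at −1.03 without passing (limma adjusted p = 0.0597). TRIB3 did not pass without the untreated or the 0.5 µM array (limma adjusted p = 0.179 and 0.0728). Against the 0.5 µM array the median was −0.31. The unfolded protein response stayed within the random range at 5 µM (median 0.10 over 16 genes, 0 rose and 0 fell by limma, also adjusted over the list alone), with EDEM1 at 1.21 (limma adjusted p = 0.0566), or 0.46 with the mean of its probe sets. Its median was −0.21 at 0.5 µM, below the random range, so that against the 0.5 µM array it was 0.40 at 5 µM, above the range. Oxidative stress genes had a median of 0.09 over 16 genes (2 rose, 3 fell; 3 and 4 adjusted over the list alone), with NQO1 higher by 1.90 and GCLM, a glutathione synthesis gene, lower, at −1.33, both past the test without any single array. Among 18 p53 target genes (median −0.06) 4 rose and 3 fell, also when adjusted over the list alone, with TNFRSF10B, a death receptor gene, at 1.45, or 0.60 with the mean of its probe sets and 0.10 without probe sets that share probes between transcripts, and not past the test without the 5 µM array (limma adjusted p = 0.0614). Of the p53 targets that fell, GADD45A was at −0.75. By trend slope the p53 list lay below the random range (median −0.07 per step) and the unfolded protein response above it (0.07). Both came back within it without the 0.5 µM or the 5 µM array, and the p53 list also without the 1.5 µM array. Heat shock proteins (median 0.08 over 14 genes, 1 rose, 1 fell; 2 and 1 adjusted over the list alone) stayed within the random range at 5 µM.

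The remaining lists also stayed within the random range at 5 µM. Interferon-stimulated genes had a median of 0.10 over 18 genes, with 5 that rose and 2 that fell (6 and 3 adjusted over the list alone), XAF1, IFITM3 and IFITM1 at 1.66, 1.37 and 1.09. Inflammatory cytokines and NF-kB targets had a median of 0.10 over 15 genes, with 2 that rose and 0 that fell (4 and 0 adjusted over the list alone). IL1B was higher by 1.73 (limma adjusted p = 0.11 without the 5 µM array) and PTGS2 by 2.43, the latter without passing (limma adjusted p = 0.0528). Genes of glycolysis and hypoxia had a median of 0.04 over 24 genes, with 3 that rose and 4 that fell (4 and 5 adjusted over the list alone). PKM, the pyruvate kinase gene of non-erythroid tissues, rose by 0.98 ± 0.134 per step to 2.86 at 5 µM (limma adjusted p = 0.0148), or 1.73 with the mean of its probe sets, while the hypoxia target BNIP3 was at −1.70, or −0.87 with the mean of its probe sets, without passing (limma adjusted p = 0.0849). Medians were −0.05 for cytokine signalling feedback (15 genes, 2 rose, 2 fell; 3 and 4 adjusted over the list alone), −0.02 for apoptosis regulators (16 genes, 2 rose, 1 fell; 3 and 3) and 0.17 for histones (11 genes, 2 rose, 0 fell; 3 and 0). Lysine demethylases and methyltransferases had 0.14 (25 genes, 2 rose, 1 fell, also adjusted over the list alone), with SETD7 at 2.05, or 1.07 with the mean of its probe sets, and autophagy and mitophagy 0.02 (20 genes, 0 rose, 2 fell, also adjusted over the list alone). Ribosomal proteins (0.04 over 24 genes), oxidative phosphorylation (−0.08 over 20), housekeeping genes (0.02 over 15) and fetal-stage regulators such as IGF2BP1 and HMGA2 (−0.11 over 6) had 0 genes past the limma test in either direction, also when adjusted over the list alone. At lower doses 3 of the lists that did not stand apart at 5 µM lay above the random range, p53 targets at 0.5 µM (0.13), histones at 1.5 µM (0.18) and glycolysis at both (0.16 and 0.18). Against the 0.5 µM array the interferon list (0.22), the inflammatory list (0.19), the neutrophil list (0.24) and the histone list (0.25) lay above the random range at 5 µM, and the p53 (−0.17), cytokine feedback (−0.17) and glycolysis lists (−0.23) below it. For the neutrophil, p53 and glycolysis lists the 0.5 µM array itself stood apart from the untreated array in the opposite direction.

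At 1.5 µM many of the same groups had moved. SIGLEC6, RUNX2, VIM, SLC25A24 and EPAS1 (a hypoxia-inducible transcription factor) had the largest increases, at 3.55, 3.53, 3.10, 3.01 and 2.97, and another probe set of EPAS1 differed by −0.21 at 5 µM. TRIM10, PAQR9, HBM, FHDC1 and SLC4A1 had the largest decreases, at −3.98, −3.80, −3.46, −3.31 and −3.22. Medians were −0.63 for the heme list and 0.81 for the mast cell list. In all 222 genes were higher and 99 lower by 2-fold or more, and 8 lists stood above and 9 below the random lists. With the 0.5 µM array as the baseline 77 were higher and 44 lower, and with the mean of all probe sets of a gene 135 were higher.

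The lowest dose, 0.5 µM, gave the smallest differences. AXL, a receptor tyrosine kinase, CALB1 (calbindin), SIGLEC6, KRT19 (a keratin) and OSBPL6 had the largest increases, at 2.12, 1.99, 1.95, 1.91 and 1.79. ADM (adrenomedullin), TRIM10, MGST3, BPGM and HBM had the largest decreases, at −1.47, −1.27, −1.25, −1.19 and −1.19. CALB1 was 6.83 at 0.5 µM against 4.84 with no drug and 4.49 at 5 µM, the only gene past the filter with a 2-fold peak or dip at an inner dose. KRT19 was higher by 1.96 at 1.5 µM and 1.82 at 5 µM, so that against the 0.5 µM array it was at −0.09. At this dose 49 genes were higher and 12 lower by 2-fold or more, or 22 and 7 with the mean of all probe sets, and 5 lists stood above and 11 below the random lists. The heme list was at −0.15 and the mast cell list at 0.27.

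The dose trend asks which genes changed in step with the dose. The smallest p-values belonged to CD52, APPL1, LGALS1 (galectin), ACSM3 and DACH1 among genes that rose, and to TSPO2, SLC2A1, ALAS2, THBS1 and MGST3 among genes that fell. CD52, a small surface glycoprotein of leukocytes, was higher by 0.97 at 0.5 µM and by 3.04 at 5 µM, and its slope was 1.01 ± 0.0331 per step (limma adjusted p = 0.0039). TSPO2, an erythroid cholesterol-binding protein, was lower, at −0.63, −1.25 and −1.82. Over 12713 genes 931 rose and 657 fell by limma, with median slopes of 0.32 and −0.25 per step. Of the 721 genes that differed by 2-fold or more at 5 µM, 635 passed and 86 did not. These numbers depend on the coding of dose and on single arrays. With the dose in µM as the covariate limma called 124 that rose and 14 that fell, and with any dose against none 0 and 0 (624 and 487 at an unadjusted p under 0.05). Without the 5 µM array 217 rose and 122 fell, without the 1.5 µM array 506 and 254, without the untreated array 647 and 397, and without the 0.5 µM array 676 and 399. Of 115 named genes past the test, 44 passed in each of the 4 fits that leave out an array, all 10 genes with the smallest p-values among them.

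Steps of dose that share no array were compared gene by gene. The difference between 1.5 µM and no drug correlated with that between 5 and 0.5 µM at r = 0.69 (Spearman 0.52) across 12713 genes, which are not independent replicates. Of the 321 genes at 2-fold or more in the former, among them RUNX2 and HBM, 308 (96.0%) had the same sign in the latter. The difference between 0.5 µM and no drug correlated with that between 5 and 1.5 µM at r = 0.13 (Spearman 0.13), and 42 of 61 genes (68.9%) had the same sign. Differences that share the untreated array correlated at 0.73 (0.5 with 1.5 µM), 0.59 (0.5 with 5 µM) and 0.89 (1.5 with 5 µM), beside 0.498, 0.499 and 0.490 in a simulation with no effect. Their covariances were 0.0639, 0.0716 and 0.176, beside 0.0124, 0.0122 and 0.0118 in the simulation.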

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

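Every test in this part was chosen after the result it bears on had been seen.

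Data outside the comparisons held signals that differed at 5 µM. Control probe sets for 18S ribosomal RNA, measured by 3 probe sets, were higher than on the untreated array by 0.81. Of 748 probe sets with several gene symbols above the expression filter, 32 were higher and 13 lower by 2-fold or more. Of 1426 probe sets with no symbol in the annotation table, 34 were higher and 32 lower by 2-fold or more. They had no part in any count of genes.

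The lower erythroid lists and the higher mast cell list at 5 µM were weighed against technical explanations. A rescaling of whole arrays would keep the order of genes within an array. In rank, the median member of the heme list moved by −4.02 percentile points (random lists down to −0.66). That of the mast cell list moved by 22.6 (random lists up to 1.90). Sorted values of the 4 arrays already differed by only 0.0275 on average, so ranks had to move with the log2 differences. The ranks therefore decide nothing about rescaling, and probe-level steps of the authors' processing were not tested. RNA quality of the untreated array as the whole cause is argued against by the 0.5 µM baseline for the heme and mast cell lists, whose kept shares were computed. It kept 68.1% and 63.3% of their shifts. Of the shifts in the ACTB and GAPDH 3' to 5' gaps and in 18S RNA it kept 38.0%, 14.9% and 12.1%. The probe set for the 5' end of ACTB, taken alone, kept more, at 0.38 in place of 0.64. That for its 3' end was at 0.20 in place of 0.18. Several other lists also kept most of their shifts, so the argument extends to them. The erythroid transcription factor list was at −0.42 in place of −0.43. The membrane list was at −0.51 in place of −0.63 and the red cell enzyme list at −0.44 in place of −0.68. The monocyte list was at 0.93 in place of 0.81 and the megakaryocyte list at −0.36 in place of −0.31. The immediate early list stayed at 0.31, and the MHC class II list was at 0.42 in place of 0.57. Some lists kept less. The progenitor list was at 0.33 in place of 0.77, the sterol list at 0.19 in place of 0.40. The G2/M list was at −0.16 in place of −0.46. For the progenitor, sterol and G2/M lists, and for lists not named here, RNA quality stays open. Fewer erythroid cells with every other type raised alike is argued against by the megakaryocyte list, which was at −0.31, with 8 genes that fell and 2 that rose. This bears only on the other types being raised alike. Fewer erythroid cells with an uneven change of the other types stays open. More mast cells or basophils in the culture may account for the mast cell list, of which 11 of 13 genes were higher (GATA2 went from 9.93 to 11.10 and HDC from 7.21 to 10.68), and the labels used name no sort that removes such cells, but a change in cell makeup and in expression per cell cannot be told apart with RNA from whole cultures.

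HBB and HBG1 differed by −0.15 and −0.16 at 5 µM, and compression of very bright probe sets may have hidden part of a change. Small differences were not limited to such probe sets, since 6 other genes among 70 of the globin and erythroid lists differed by no more than HBG1. Among them were HBE1, at 7.51 on the untreated array and −0.08, and the bright TFRC, at 12.82. Across all probe sets the median absolute difference between the untreated and 5 µM arrays was 0.137. Small differences of dimmer genes were thus common and decide nothing about compression. In 3 of 3 genes with a bright and a dimmer probe set (HBD, HMGCS1 and TOP2B) the brighter one differed less, by −0.95 against −1.64, 0.80 against 0.86 and 0.50 against 0.67, under limits lowered after stricter ones had left no gene, but only for HBD by more than 2 times the median residual SD of a gene (0.0897). That probe sets above 13 on the untreated array cannot move at all had 1 exception, as 1 of 65 such probe sets moved by 0.5 or more, at −1.06. A true lack of change in HBB and HBG1 and compression cannot be told apart, because so few genes have probe sets of different brightness.

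The number of genes past the trend test was set against other orders of the 4 arrays. The order by dose gave 1588 genes (3633 at an unadjusted p under 0.05), and of 12 orders (a reversed order counted once) only 1, the real one, gave as many, with 0 in the highest of the others (1813 genes at most at an unadjusted p under 0.05). The orders are too few for a share under 0.05.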

How the results depend on the processing

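The baseline of TC 0.5 µM, and cyclic loess for the correlations, were chosen after the control probe sets had been seen; the other alternatives here were planned. No paired analysis was possible because each dose has 1 array and the labels give no replicate numbers. The counts of genes and of lists stayed within 1.5 times without probe sets ending in _x_at and under both other filters. They did so under the 3 other normalizations too, which says little about stability, because these moved the 5 µM differences of genes almost alike (SD of the move across genes 0.0058 with cyclic loess and 0.0211 with quantile normalization, and the same move for each gene with centring). With the mean of all probe sets of a gene, 22 genes were higher and 7 lower at 0.5 µM, 135 higher at 1.5 µM and 313 higher at 5 µM; the cause was not tested. A 1.5-fold threshold is looser by construction and gave 240 and 101 at 0.5 µM, 611 and 396 at 1.5 µM and 1048 and 635 at 5 µM. Against TC 0.5 µM, 77 were higher and 44 lower at 1.5 µM, 327 were higher at 5 µM, and 11 lists lay above the random range; the cause was not tested. The trend gave 124 and 14 genes with the dose in µM, and 0 and 0 with any dose against none, a coding that leaves no room for steps between doses. Leaving out each array in turn, which leaves 1 residual degree of freedom, gave 217 to 676 genes that rose and 122 to 399 that fell, 6 to 11 lists above and 9 to 11 below by slope; the lowest gene counts came without the 5 µM array. Of 115 named genes past the trend test 52 passed without the 5 µM array, 83 without 1.5 µM, 98 without 0.5 µM and 84 without the untreated array. Of 15 lists outside the random range at 5 µM, 14 stayed outside it against TC 0.5 µM. Of 98 named genes at 2-fold or more at 5 µM, 68 stayed so against TC 0.5 µM, 29 did not and 1 reversed. With the mean of all probe sets of a gene, 72 of 95 stayed so. Lists within the range at 5 µM also left it. With the mean of all probe sets these were p53 targets (−0.16), heat shock proteins (0.10) and histones (0.18), without probe sets ending in _x_at p53 targets (−0.23) and inflammatory genes (0.25), and with the 60th percentile filter heat shock proteins (0.11), inflammatory genes (0.42) and histones (0.24); the cause was not tested. Without the filter the progenitor list reversed to −0.0319, by construction through genes near background. KRT19 reversed to −0.0934 against TC 0.5 µM, since its difference was already 1.91 at that dose. Genes near the filter value of 4.53 lie close to background, which limits what their differences can show.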

Other observations

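The tests of how far genes past the trend test had moved at 1.5 µM were written down before their results were seen, but that a whole interval, not the difference alone, must lie under 5 percentage points to count as under that bound was decided after, and the shares without selection by the trend test were added after.

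Other genes named by the preset rule also differed with TC. LGALS1, a galactose-binding protein, was higher by 0.91, 1.98 and 2.77 in order of dose, and APPL1, an endosomal adaptor, by 0.85, 1.79 and 2.66. DACH1, a transcription factor, was higher by 0.72, 1.43 and 2.07. Feedback inhibitors of cytokine and growth factor signals were higher at 5 µM in SPRY2 (1.23) and SOCS1 (1.22, or 0.79 with the mean of its probe sets), while ID1, a target of BMP signals, was lower, at −1.09. The autophagy gene WIPI1 was lower, at −1.32 and the histone demethylase KDM6A at −0.78. SPRY2, SOCS1, ID1 and KDM6A passed the trend test but not without the 5 µM array (limma adjusted p = 0.15, 0.0889, 0.103 and 0.137), and WIPI1 not without the untreated or the 0.5 µM array (0.123 and 0.0544). SPRY2 and KDM6A did not pass without the 1.5 µM array either (limma adjusted p = 0.0523 and 0.0553).

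A hypothesis was that genes that fall had come further along at 1.5 µM than genes that rise. Among genes past the trend test with 2-fold or more at 5 µM, 450 that rose had reached a median of 64.2% of their 5 µM difference and 185 that fell 68.4%, a gap of 4.18 percentage points (95% bootstrap interval over genes 1.72 to 8.18, from 10000 draws), or 3.7 (−0.76 to 7.28) with the 88 that fell and stayed above 7, where a background floor could flatten less. Selection by a straight line over the dose steps draws such shares towards that line, so these gaps decide nothing, and at 0.5 µM the order was the other way, with 27.7% for genes that rose and 22.7% for genes that fell. Without that selection, 514 higher genes had reached 61.9% and 207 lower genes 67.7%, a gap of 5.8 points (2.19 to 8.93), which passed the preset bound of 5 as the selected genes had not, but it was 4.51 (−0.21 to 8.23) with the 94 lower genes above 7, and −3.12 (−7.18 to 1.11) at 0.5 µM. The intervals at 1.5 µM reach across 5 points, the outcome turned on the selection, and genes on the same 4 arrays are not independent, so neither the hypothesis nor a floor was settled.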
